A study of Caenorhabditis elegans with 2 samples.

How the data were processed

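The data were peak lists from chromatin immunoprecipitation followed by sequencing (ChIP-seq), in which DNA bound by a protein is pulled down with an antibody and sequenced. The protein was ALR-1, a paired-like homeodomain transcription factor of Caenorhabditis elegans related to Drosophila Aristaless, tagged with eGFP and carried by an integrated transgene. Per the labels, 2 biological replicates of whole worms of mixed sex at the second larval stage (L2) were used, and both fell into 1 group. The comparisons were therefore between replicates, and between classes of regions within the lists. A control library was not analysed here.

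Per the file notes, the authors called candidate regions on each replicate with a control, called them again on both replicates together (the pooled list), and derived from these an optimal list thresholded by the irreproducible discovery rate (IDR), a measure of how consistently regions rank in replicates. The candidate lists hold peaks together with background regions as input for that procedure, so a candidate region is not a called peak. Each list was deposited on the genome builds ce10 and ce11. The aligner, the peak caller and the IDR threshold are not given in the sources used here. Each deposited region has a signal value from the authors' caller, whose scale is not stated, and a q-value which by the format of the deposited file is a −log10 value. The −log10 q-values reached a ceiling of 2.90 in the pooled ce11 list, shared by 402 regions, so regions were ranked by signal. Signal values were used to rank and describe regions within a list. Read depth is unknown, since the lists give no read counts, and no precision could be derived from it. Within a list all regions had the same width, with the point source at the middle.

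Coordinates were compared with the assembly WBcel235, which is the sequence of ce11. All ce11 regions lay inside its chromosomes. The ce10 lists were used only for counts, to find their IDR peaks in their own pooled list, and for the overlap of the replicates, and no coordinates were converted. Genes came from Ensembl release 115, with 19973 protein-coding genes on the 6 nuclear chromosomes. A region's point was placed in a promoter when it lay from 1000 bp upstream to 200 bp downstream of a protein-coding transcript start, and otherwise in an exon, an intron or intergenic sequence, in that order. Overlap with the 1107 annotated tRNA, rRNA, snRNA and snoRNA genes was counted apart. The nearest protein-coding transcript start within 3000 bp gave the gene beside a region.

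IDR peaks were compared with the 12875 pooled candidates that overlapped none of them, by Fisher's exact test, two-sided, for promoter location, location on X, and the presence of TAATTA or TAATNNNATTA on either strand within 100 bp of the point. These 4 tests formed 1 family with Benjamini-Hochberg adjustment. All 36 hexamers made of A and T, with reverse complements joined, were ranked by the same odds ratio. Shares have exact Clopper-Pearson 95% intervals, which treat regions as independent. Regions and genes are not biological replicates, so these p-values describe the lists and not the spread between animals. For 21 gene lists, members beside an IDR peak were compared with the 6831 genes that had any pooled candidate within 3000 bp, by Fisher's exact test, one-sided, with Benjamini-Hochberg adjustment over the 21 lists. The overlap of the 103 strongest regions of each replicate (at least 1 bp) was compared with 1000 random placements on the same chromosomes, for which the ce11 chromosome lengths also served the ce10 lists. Correlations used 100000 permutations, two-sided, across peaks.

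The gene lists, tests and alternative settings were fixed before the data were examined. So was the rule for named genes: alr-1, the genes of the 15 strongest IDR peaks, members of the homeobox and touch receptor neuron lists with an IDR peak, and members of any other list that passed. Other genes were named after their values were seen, and the text says where. The alternatives covered a stricter set of peaks, each replicate alone, other promoter, motif and assignment windows, other comparison regions, other overlap rules and the ce10 lists. For promoter, X and motif shares, the strongest regions of a replicate alone were compared with the pooled candidates that overlapped none of them. Those comparison regions therefore still rest on both replicates. For gene lists the background also changed, to 3287 genes with replicate 1 alone and 4442 with replicate 2 alone. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The code was tested on simulated data. With the motif planted in a further 10% of 103 candidates drawn at random from 12875, the TAATTA test passed 0.05 in 87 of 100 simulations, and with none planted in 2. Of those 12875 candidates 7.98% held TAATTA, against 4.75% of candidates with the GC content of the IDR peaks. That lower share was not simulated, so 87 is likely too high for the IDR peaks. With members of a gene list drawn 5 times as often among 6831 genes, the list was called in 18 of 100 simulations, and at 10 times in 48.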

Results

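Regions bound by eGFP-tagged ALR-1 were mapped in whole L2 larvae of the strain OP200, which carries the tagged gene as a transgene in an unc-119 mutant background. ALR-1 is known for roles in the development of sensory and motor neurons, including the touch receptor neurons. The group had 2 biological replicates. On ce11, replicate 1 had 5071 candidate regions of 390 bp, replicate 2 had 7568 of 304 bp, and the pooled list had 12996 of 320 bp. The optimal IDR list held 103 peaks. These were the 103 pooled regions with the highest signal (0.793% of the list), from 49.8 down to 21.3 in the units of the authors' caller. On ce10 the counts were 5070, 7456, 12942 and 93, and all 93 IDR peaks were again the strongest pooled regions. The depth of the libraries is unknown.

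The strongest IDR peak lay at ceh-38, which encodes a ONECUT-class homeodomain protein (II:6951392-6951711, signal 49.8, point 26 bp downstream of a transcript start). The peak overlapped regions of rank 9 in replicate 1 (signal 14.7) and rank 2 in replicate 2 (signal 30.9). The second lay in an intron of zfp-1, a gene for a PHD-finger chromatin protein, at III:8802008-8802327, 651 bp upstream of an internal zfp-1 start. Its signal was 48.9, and the overlapping regions ranked 84 in replicate 1 and 1 in replicate 2. The gene body of zfp-1 (III:8791535-8806305) held 4 IDR peaks, of ranks 2, 10, 17 and 40. The peak of rank 10 was nearest to F54F2.6, at 533 bp. The peak of rank 17 had no region in replicate 1. The third strongest peak was 361 bp upstream of syd-2, which encodes the presynaptic scaffold protein liprin-alpha (X:10555440-10555759, signal 43.8).

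The other genes beside the 15 strongest peaks were as follows. The peak of fkh-7, a forkhead factor gene, lay in an intron at IV:5604522-5604841, with a signal of 37.3 and ranks of 6 and 14 in replicates 1 and 2. A further IDR peak of rank 48 lay 861 bp upstream of another fkh-7 start. A peak 2 bp upstream of met-1, a histone methyltransferase gene, had a signal of 33.9 (I:4254035-4254354). The bZIP factor gene let-607 had a peak 100 bp upstream, with a signal of 31.2 (I:6579762-6580081). The peak 284 bp upstream of puf-9, a Pumilio-family gene, ranked first in replicate 1 and 237 in replicate 2 (X:5841148-5841467, signal 34.3). An intronic peak of larp-1, which encodes a La-related RNA-binding protein, had a signal of 31.6 (III:5013983-5014302). Promoter peaks lay beside mrps-17, for a mitochondrial ribosomal protein (III:6431797-6432116, signal 36.8), and the elongation factor gene eef-1A.2 (X:7823009-7823328, signal 33.4). The calmodulin gene cmd-1 had an intergenic peak 2174 bp upstream (V:1153937-1154256, signal 36.8). Peaks beside Y17G9B.5 (IV:4749903-4750222, signal 41.5) and F36A2.7 (I:8813292-8813611, signal 31.3) lay in promoters. The remaining peak, at X:13145342-13145661 with a signal of 35.8, was 3901 bp from the nearest start, that of F09A5.3, and was assigned to no gene. All 15 peaks overlapped a region in each replicate. Of the 15, 10 were among the 103 strongest regions of replicate 1 and 13 among those of replicate 2.

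The alr-1 gene itself (X:11121871-11125620, minus strand) was the nearest gene of 4 IDR peaks, all upstream of its start in intergenic sequence. They lay 1796, 3644, 9565 and 12067 bp from the start, with signals of 22.1, 21.97, 26.5 and 24.4 and ranks of 81, 84, 37 and 55. The closest of them was within 3000 bp. In the pooled list, 21 regions had alr-1 as the nearest gene, where the median gene with any region had 1. They spanned X:11123691-11138057, and 2 genes had more. Replicate 1 had 11 such regions and replicate 2 had 21, with best ranks of 74 and 23. A further IDR peak, of rank 63, lay in the promoter of the neighbouring gene R08B4.3 (X:11120789-11121108), which was named after its value was seen. Since the transgene carries alr-1, reads from the locus can come from the transgene as well as from the chromosome.

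**Figure D1:**
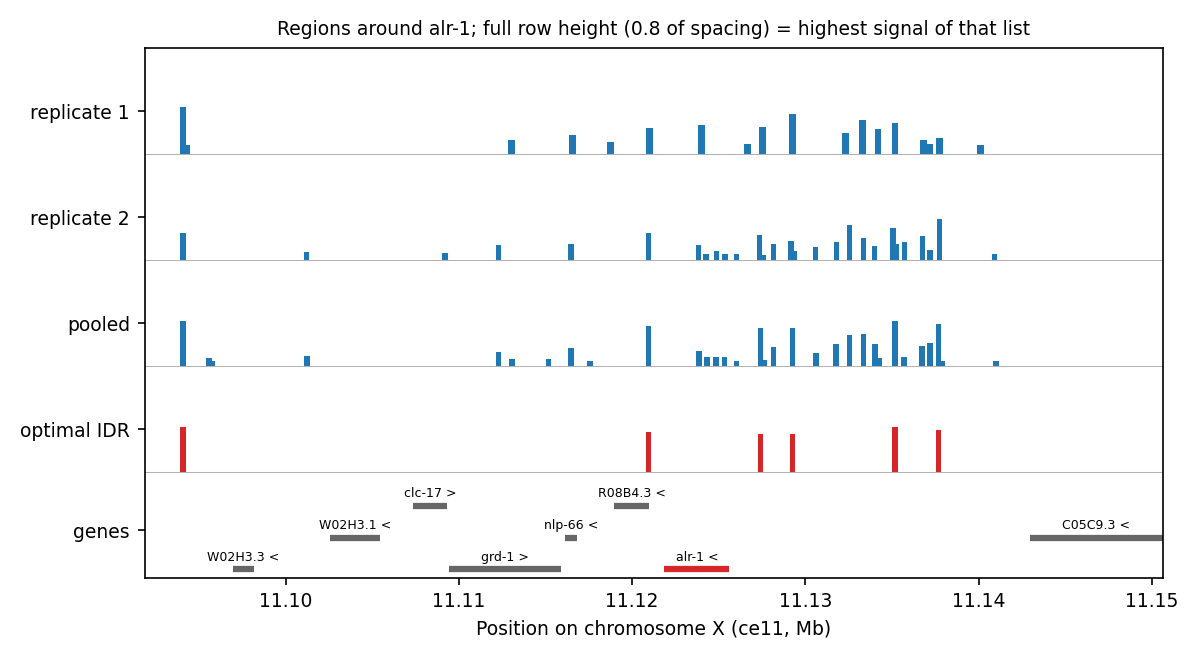
Map of candidate regions and IDR peaks around alr-1 on chromosome X (ce11, position in Mb), with 1 row per list and protein-coding genes below, where > and < give the strand. The bar height is a region's signal relative to the highest signal of its own list. The pooled list has 21 regions nearest to alr-1, and 4 of them are IDR peaks.

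Agreement between replicates was measured on their strongest regions. Of the 103 strongest regions of replicate 1, 14 (13.6%) overlapped 1 of the 103 strongest of replicate 2, against 0.0893% on average over random placements (permutation p = 0.000999, one-sided, the smallest that 1000 placements can give). When 103 regions were drawn at random from replicate 2's own list, a reference chosen after seeing the data, the share was 1.18% on average and at most 6.80%. Over the full lists, 1648 of 5071 regions of replicate 1 (32.5%) overlapped a region of replicate 2, against 5.27% by random placement. IDR peaks overlapped a region of any rank in replicate 1 in 87 of 103 cases (84.5%, 95% interval 76.0 to 90.9) and in replicate 2 in 100 cases (97.1%, 91.7 to 99.4). These peaks come from a list called on both replicates together, so part of this overlap is built in. A region in both was found for 84 peaks. Among the 103 strongest regions of both replicates were 13 IDR peaks, and 23 were among those of neither. Across the 84 peaks with a region in both, signals in the 2 replicates were inversely related. These peaks were among the strongest of the pooled list, and a choice on pooled signal can by itself make the relation inverse. The permutations do not allow for that choice, so the p-values at these peaks do not show that the replicates disagree. Pearson's r was -0.23 (permutation p = 0.0347, adjusted 0.0347) and Spearman's rho was -0.31 (permutation p = 0.00425, adjusted 0.0085, family of 2). Without the 2 peaks farthest from the replicate 1 median, r was -0.19 (permutation p = 0.0847) and no longer passed the test, while rho was -0.28 (permutation p = 0.0113). On log2 signals of all 84 peaks, r was -0.30 (permutation p = 0.00593). Across all 1724 pooled candidates with a region in both replicates, an alternative chosen after seeing the data, rho was 0.23 (permutation p = 1e-05, the smallest that the permutations can give).

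**Figure D2:**
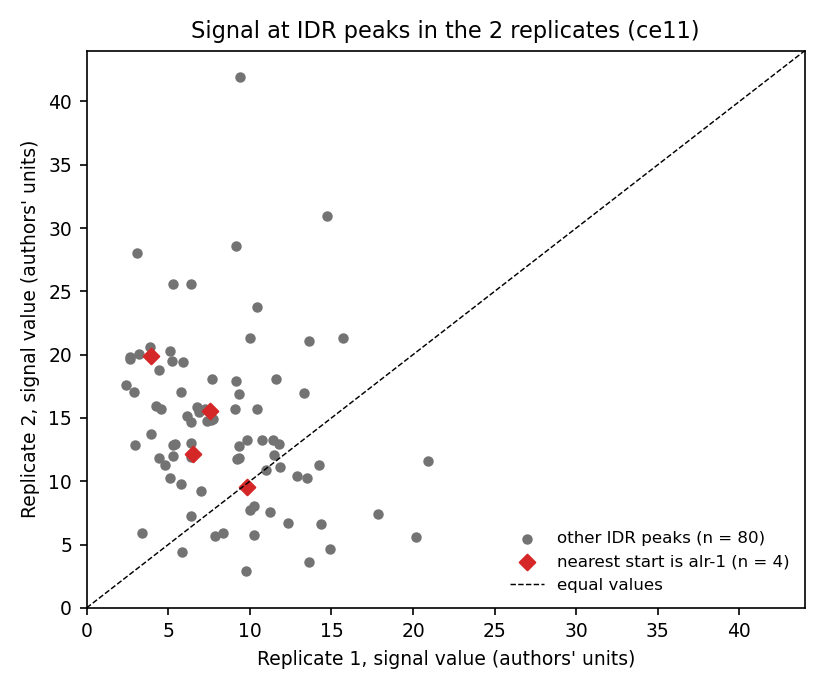
Signal value of the strongest region overlapping each IDR peak in replicate 1 (x axis) and replicate 2 (y axis), in the units of the authors' caller, for the 84 IDR peaks with a region in both. Diamonds mark the 4 peaks nearest to alr-1, and the dashed line marks equal values. Signals were inversely related across peaks, with r = -0.23, which the choice of peaks on pooled signal can by itself produce.

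IDR peaks lay in promoters more often than other candidates. Promoters held 56 of 103 IDR peaks (54.4%, 95% interval 44.3 to 64.2), among them those of ceh-38, syd-2 and met-1, and 5169 of 12875 other candidates (40.1%, 39.3 to 41.0). The odds ratio was 1.78 (95% interval 1.18 to 2.68, Fisher's exact p = 0.00451, adjusted 0.018 over 4 tests). It did not pass the test for the 51 strongest peaks (1.68, Fisher's exact p = 0.0849) or for promoters reaching 2000 bp upstream (1.49, Fisher's exact p = 0.0583). It did for promoters from 500 bp upstream to 100 bp downstream (2.22, Fisher's exact p = 8.92e-05). Intergenic sequence held 28 IDR peaks (27.2%), introns 18 (17.5%) and exons outside promoters 1 (0.971%), against 26.4%, 21.5% and 11.95% of the other candidates. The exon share, outside the family of 4 tests, had an odds ratio of 0.0722 (Fisher's exact p = 4.85e-05). A lack of IDR peaks in exons thus describes the lists as well as an excess in promoters does. The promoter share was 53.7% for the pooled regions ranked from there to 500 and 33.7% for ranks 8001 to 12996. Against the next 103 regions by rank the promoter odds ratio was 1.21 (Fisher's exact p = 0.577), so the IDR peaks were not shown to differ from the regions ranked just below them. With the 103 strongest regions of replicate 1 alone, against the pooled candidates that overlapped none of them, the promoter odds ratio was 1.30 (Fisher's exact p = 0.191). With those of replicate 2 alone it was 2.17 (Fisher's exact p = 0.000109). A tRNA, rRNA, snRNA or snoRNA gene overlapped 2 IDR peaks (1.94%) and 253 other candidates (1.97%).

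The X chromosome, which carries alr-1, syd-2 and puf-9, held 28 of 103 IDR peaks (27.2%, 95% interval 18.9 to 36.8) and 24.0% of the other candidates. The odds ratio of 1.18 (0.737 to 1.85) did not pass the test (Fisher's exact p = 0.487, adjusted 0.806). Chromosome III held 21 IDR peaks and chromosome II held 10.

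TAATTA, the core sequence bound by many homeodomain proteins, was present within 100 bp of 8 IDR peak points (7.77%, 95% interval 3.41 to 14.7). Among the 15 strongest peaks it was found only at mrps-17. The share among other candidates was 7.98% (7.51 to 8.46), and the odds ratio of 0.971 (0.406 to 2.00) did not pass the test (Fisher's exact p = 1.0, adjusted 1.0). The paired-type palindrome TAATNNNATTA was present at 1 IDR peak (0.971%) and 0.893% of other candidates, with an odds ratio of 1.09 (0.027 to 6.32, Fisher's exact p = 0.605, adjusted 0.806). With the strongest regions of replicate 1 or replicate 2 alone, the odds ratio was 0.712 or 1.24 for TAATTA and 0.0 or 2.20 for TAATNNNATTA, so neither kept its direction. TAATTA ranked 2 of 36 A/T hexamers by odds ratio, and the median odds ratio of the other hexamers was 0.562. GC content within 100 bp of the point was 43.96% ± 5.89 (SD across regions) for IDR peaks and 38.3% ± 6.58 for other candidates. Against candidates of the same GC content, of which 4.75% held TAATTA, the odds ratio was 1.69. For each IDR peak a candidate within 1 percentage point of its GC content was drawn at random, 10000 times. The two-sided p from these matched draws was 0.227.

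**Figure D3:**
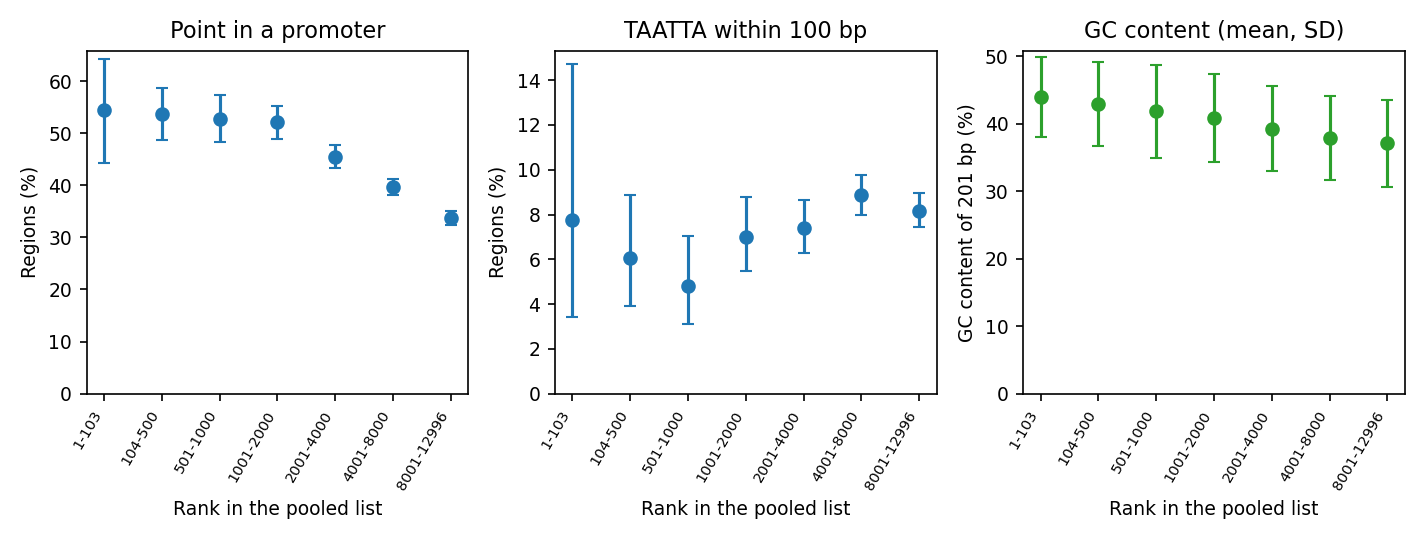
Promoter location (left), TAATTA within 100 bp of the point (middle) and GC content of 201 bp around the point (right), all in percent, for pooled regions in 7 bins of rank by signal. Points are shares with exact 95% intervals, or means with the SD across regions for GC content. The promoter share ran from 54.4% in the first bin to 33.7% in the last, and the TAATTA share lay between 4.8% and 8.85%.

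Genes beside IDR peaks were then grouped by the 21 gene lists. Of 103 peaks, 84 lay within 3000 bp of a start, beside 81 genes. No list passed the adjusted threshold of 0.05 by Fisher's exact test, and 1 list had an unadjusted p below 0.05. This list was heat shock and stress genes, with 3 of 61 members beside a peak (odds ratio 4.44, Fisher's exact p = 0.0354, adjusted 0.668). With the strongest regions of replicate 1 or replicate 2 alone, the odds ratio was 1.43 or 2.58. The members beside IDR peaks, named after their values were seen, were the hypoxia factor gene hif-1, the unfolded protein response factor gene xbp-1, and ugt-50, which encodes a UDP-glucuronosyltransferase. Homeobox genes had 2 of 39 members beside a peak, ceh-38 and alr-1 (odds ratio 4.59, Fisher's exact p = 0.0776, adjusted 0.668). The odds ratio was 2.27 with replicate 1 alone, 2.03 with replicate 2 alone and 2.33 without the alr-1 region, a setting chosen after seeing the data. Of the touch receptor neuron genes, 1 of 17 had a peak, alr-1 itself (odds ratio 5.26, Fisher's exact p = 0.184, adjusted 0.772). It was 4.81 with replicate 1 alone, and 0.0 with replicate 2 alone or without the alr-1 region, a setting chosen after seeing the data. The member with replicate 1 alone was not alr-1. The only alr-1 region among the 103 strongest there, of rank 74, lay 3644 bp from the start, beyond the 3000 bp used.

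Of the 6831 genes with a candidate nearby, 81 lay beside an IDR peak, and 6 further lists had 1 or 2 members among them. Nuclear hormone receptors had 2 of 96 members beside a peak, nhr-17 and nhr-19. The list of bHLH and zinc finger developmental regulators had 2 of 44, which were the forkhead gene fkh-7 and the doublesex-related gene dmd-7. Panneuronal genes had 1 of 27 (syd-2), Wnt pathway genes 1 of 13 (mig-5, a Dishevelled gene), germline genes 1 of 21 (puf-9), and ribosomal protein genes 1 of 45 (rpl-12). The germline list took in all puf genes by family name, so puf-9 does not by itself point to the germline. The members other than fkh-7, syd-2 and puf-9 were named after their values were seen. The odds ratios of these 6 lists, set apart by having a member beside a peak, ran from 1.79 for nuclear hormone receptors to 7.02 for Wnt pathway genes, and none passed the test (Fisher's exact adjusted p between 0.668 and 0.972). With replicate 1 or replicate 2 alone they were 0.748 or 0.0 for nuclear hormone receptors, 0.0 or 4.88 for Wnt pathway genes, 4.81 or 0.0 for germline genes and 0.0 or 2.21 for ribosomal protein genes. Those of the developmental regulators (3.64 or 4.28) and the panneuronal genes (5.47 or 3.93) stayed above 1. The members can differ between settings, since 2 panneuronal genes lay beside the strongest regions of each replicate alone. These ratios therefore do not show that the named members recur. The other 12 lists had no member beside an IDR peak. They were GABA neuron genes (8 genes in the background), amphid chemosensory neuron genes (9), ciliogenesis genes (14), neuropeptide genes (50), axon guidance and adhesion genes (40), DEG/ENaC, TRP and nicotinic receptor channels (34), epidermis and seam genes (29), cuticle collagens (49), body and pharyngeal muscle genes (26), intestine genes (63), histone genes (10) and chemoreceptor genes (143). Among these, the axon guidance list had 1 member beside the strongest regions of replicate 1 alone, and the muscle and intestine lists had 1 each with replicate 2 alone. With 81 genes the test had little reach, since a list favoured 5 times over was called in 18 of 100 simulations. The simulations took the lists in turn, so this is an average over lists of 8 to 143 genes and does not hold for each list.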

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

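Random genomic positions, the set without the alr-1 region, random choice from replicate 2 and the set of all pooled candidates were chosen after seeing the data, and all other settings were planned. No paired analysis was possible because there was 1 group. Values are odds ratios unless another measure is named. For promoter, X and motif shares, the settings with each replicate alone kept pooled candidates as the comparison. For gene lists these settings had smaller backgrounds, of 3287 genes for replicate 1 and 4442 for replicate 2. The promoter odds ratio (1.78) stayed above 1 throughout but no longer passed the test for the 51 strongest peaks (1.68), against the next-ranked candidates (1.21), for promoters reaching 2000 bp upstream (1.49) and with replicate 1 alone (1.30), and was 2.17 with replicate 2 alone and 3.48 against random genomic positions (Fisher's exact p = 8.71e-10). The 51-peak set has fewer peaks. The next-ranked set has fewer comparison regions, and 49.5% of them lay in promoters against 40.1% of all other candidates, which lowers the odds ratio. The cause was not tested otherwise. The X odds ratio (1.18) was 0.908 against the next-ranked candidates, 0.979 without the alr-1 region, which removes 5 X peaks, 1.32 for the 51 strongest peaks, and 1.18 to 1.5 with each replicate alone, and passed the test in none of these. TAATTA (0.971) crossed 1 without passing the test for the 51 strongest peaks (1.25), in a window of 250 bp (1.10), without the alr-1 region (1.03) and matched on GC content (1.69), ranged from 0.712 to 1.24 with each replicate alone, and was 0.776 against random genomic positions. TAATNNNATTA (1.09) rested on 1 peak. It was 0.0 for the 51 strongest peaks and for a window of 50 bp, 0.327 against the next-ranked candidates and 0.363 for a window of 250 bp, and ranged from 0.0 to 2.20 with each replicate alone. The touch receptor neuron list (5.26) rested on alr-1, and was 0.0 for the 51 strongest peaks, for assignment within 1000 bp and without the alr-1 region, and 0.0 to 4.81 with each replicate alone. The 4.81, with replicate 1, came from a member other than alr-1. The homeobox list (4.59) was 2.03 to 2.27 with each replicate alone and 2.33 without the alr-1 region, and the heat shock and stress list (4.44) was 1.43 to 2.58 with each replicate alone and 1.76 for assignment within 1000 bp. No gene list was called under any of its 7 alternatives. Replicate overlap passed its permutation test under all 6 of its alternatives, from 7.77% (points within 100 bp) to 32.5% (full lists), and leaving out a replicate can give no value there. Pearson's r (-0.23) was -0.19 without the 2 farthest peaks, -0.30 on log2 signals and 0.26 over all pooled candidates with a region in both replicates, where Spearman's rho (-0.31, and -0.28 without the 2 peaks) was 0.23. The cause of each change not named was not tested. Setting the point at the interval's middle moved nothing, as the deposited points lie there. What read depth limits cannot be stated, since depth is unknown.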

Other observations

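The tests of uniform extra copies and those of GACGCA were chosen after the patterns were seen, and the tests of homeodomain sites and of selection were written before their results were seen. The following single peaks outside the named set were chosen after their values were seen, and they were not tested as a group. A peak of rank 100 lay 1918 bp upstream of hif-1, with no region in replicate 1. A peak of rank 16 lay 1740 bp upstream of the prolyl hydroxylase gene egl-9 (signal 31.2). The co-repressor gene unc-37, a Groucho homologue, had a peak 275 bp upstream (rank 67, rank 8 in replicate 1 and 2351 in replicate 2).

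The hexamer that set the IDR peaks apart with the lowest p was not a homeodomain site. Of 2080 hexamers, with reverse complements joined, 75 were more frequent and 27 less frequent in IDR peaks than in other candidates at an adjusted p below 0.05 (Fisher's exact test). GACGCA led, in 35 of 103 IDR peaks (33.98%) against 9.02% of other candidates (odds ratio 5.19, Fisher's exact adjusted p = 5.91e-09) and 3.83% of random positions. The overlapping hexamers CGTCTC, AGACGC and ACGCAG came next, and the string AGAGACGCAG was found in 14 IDR peaks (13.6%), among them zfp-1, fkh-7, met-1 and larp-1, against 2.56% of other candidates. GACGCA was present in 27.2% of the 103 strongest regions of each replicate. Among the next 103 pooled candidates by rank its share was 25.2%, and the difference from the IDR peaks did not pass the test (Fisher's exact p = 0.222). For ranks 8001 to 12996 the share was 5.8%.

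GACGCA was picked on all IDR peaks, so its explanations were tested with AGACGC, the overlapping hexamer that led on chromosomes I to III, on chromosomes IV, V and X alone, after tests of GACGCA on all chromosomes had given 13.5% in candidates matched on GC content and odds ratios of 2.87 within promoters and 9.21 elsewhere. A chance result of searching 2080 hexamers is argued against, since AGACGC had an odds ratio of 3.67 there (Fisher's exact p = 0.000167). So is GC content alone, since 14 of 57 IDR peaks (24.6%) held it against 12.1% of candidates of the same GC content. The two-sided p from 10000 random draws of GC-matched candidates was 0.0134, with 95% of draws between 5.26% and 21.1%. Outside promoters the odds ratio was 6.74 (Fisher's exact p = 2.32e-05), so the difference was not limited to promoters. That comparison was not matched on GC content or exon share, and promoter location cannot act there, so it does not test this explanation. Promoter location stays open within promoters, where 4 of 27 IDR peaks held AGACGC and the odds ratio of 1.54 did not pass the test (Fisher's exact p = 0.348). A hypothesis is that the strongest regions may be sites occupied by many factors or open in many cells, which share this sequence, and telling this from binding by ALR-1 needs other factors or a control library, not analysed here.

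The segment of 14367 bp spanned by the regions nearest alr-1 held 21 regions in the pooled list and 21 in replicate 2. Its ends were set by its own regions, and of the other windows of that length that started at a region none held more than 18 and 15. In replicate 1, however, 6 such windows held at least as many as the 11 regions there, and in the IDR list 1 held as many as the 4 peaks. Uniform extra copies of the segment, with reads spread evenly along it, are argued against as the whole cause. Of 11 regions of replicate 1, 7 had a point of replicate 2 within 100 bp, against 3.03 by chance when the points were shifted along the segment (permutation p = 0.0075). Extra copies whose reads pile up at the same places in both replicates would coincide too, so the test cannot set those apart from binding. Shifting was added after random points in the segment had given a permutation p of 0.0046. Homeodomain sites as a cause stay open, because TAATTA was present in 4 of 21 regions (19.05%) against 7.95% of other candidates, with an odds ratio of 2.72 that did not pass the test (Fisher's exact p = 0.0809), while 0 of the 4 IDR peaks nearest alr-1 held it. Extra copies from the transgene that raise existing sites or open chromatin may also account for the cluster, and the copy number and ends of the transgene were not analysed here.

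The inverse relation of the replicates at IDR peaks may follow from choosing peaks on the pooled signal, since a region high in 1 replicate then needs less from the other. Across all 1724 pooled candidates with a region in both replicates, Spearman's rho was 0.23, as that explanation predicts. Replicates that agree at all would give a positive value too, so this does not decide the question. In bins of pooled rank, rho was -0.36 for the regions ranked just below the IDR peaks, to rank 500, and -0.32 for ranks 501 to 1000. It was -0.19 and -0.06 in the bins that followed, then 0.33 for ranks 4001 to 8000 and 0.19 for ranks 8001 to 12996. Those last bins held only 228 and 97 candidates with a region in both replicates. A weak candidate beside a strong peak can overlap that peak's regions in both replicates and take their signals. Such pairs can by themselves make rho positive, so the last bins do not show whether a choice on pooled rank gives an inverse relation. The design gives no second group, so no biological explanation was tested.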
